A study of Mus musculus with 11 samples.

How the data were processed

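The study measured RNA from transduced mouse CD4 T cells on Affymetrix arrays, 1 array per sample and 11 arrays in all. Per the labels' protocols, naive CD4 T cells without CD25 and with high CD45RB were taken from lymph nodes and spleen of BALB/cA mice, activated with anti-CD3e (0.5 µg/ml), IL-2 (10 ng/ml) and splenocytes that were depleted of T cells and irradiated with 20 Gy, and spin-infected 24 h later with retrovirus made from the MIGR1 vector. Cells with high GFP were sorted on day 7, and total RNA was labelled with biotin. The groups, taken from the sample titles, were mock (empty vector, 3 arrays), WT FoxP3 (3), A384T FoxP3 (3) and R397W FoxP3 (2). The labels do not say that the arrays of a group came from separate cultures or animals, so p-values measure the spread between these arrays, which may be technical.

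The deposited table held log2 values made with RMA, per the submitters' processing notes, which give no version. RMA corrects background, normalizes by quantiles and summarizes probes to 1 log2 value per probe set. In the table, the median over the 3 mock arrays was exactly 0 at all 45101 probe sets, so each probe set had been centred on the mock arrays; this step and the base of the logarithm are not stated in the sources used here, and the base was taken to be 2, as RMA gives. Differences between arrays at a probe set are kept by such centring, whereas expression levels, and any comparison between probe sets, are lost. The array medians were 0 for mock 1, 2 and 3, -0.0043, 0 and -0.013 for WT 1, 2 and 3, 0, -0.016 and 0 for A384T 1, 2 and 3, and 0.0022 and 0 for R397W 1 and 2. The design written before the data were examined had a filter at the 30th percentile of mean signal and took each gene's probe set with the highest mean; neither can be had from centred values. All genes were therefore tested, each through the probe set with the largest standard deviation over all 11 arrays. The choice was made without the group labels, but differences between groups, or between array numbers, raise this deviation. For genes with several probe sets it therefore favours larger changes.

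Gene symbols came from the platform annotation as given for this work. Of 45101 probe sets, 34958 had 1 symbol, 932 several and 9211 none listed, and after 13 control probe sets were left out 34945 probe sets of 18193 genes remained, with more than 1 probe set for 9010 genes. Entrez identifiers of 34754 probe sets matched a RefSeq gene table (assembly GRCm38.p6), which changed 0 symbols and was used for names alone, because the genome build of the array annotation is not named. Among called genes with several probe sets, another probe set had the opposite sign for 81 of 398 in WT over mock and for 4 of 16 in A384T over WT, and none of these was called in the opposite direction.

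Each gene was fitted with limma (version 3.58.1, R 4.3.3) as 1 mean per group with all 11 arrays, and the 6 contrasts between groups were tested with eBayes. A gene was called at an adjusted p under 0.05 (Benjamini-Hochberg over the 18193 genes of a contrast). The fit had 7 residual degrees of freedom and a median residual standard deviation of 0.197. The other tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. Before the data were examined, 29 gene lists were written, 22 of T cell genes and pathways and 7 of markers of other cell types that the sort or the feeder cells could bring; 72 of their 510 genes were in more than 1 list. Because levels are lost, how many of the other cell types' markers these T cells express was not counted. Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 lists of a contrast. With a correlation estimated per list, the called lists that held were the Treg list in WT over mock, A384T over mock and R397W over WT, 3 of 33 called results. The median, the mean and the test had the same sign for all 33.

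The genes named were chosen by a rule written before the data were examined. Foxp3, Batf, Irf4, Il2ra, Ctla4, Il2, Ifng and Il7r were always named. In WT over mock, A384T over WT and R397W over WT, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap were named, and in the other contrasts the 5 largest each way. From each list, up to 4 called members with the largest change were taken, or up to 2 members where none was called, and the text names part of these. All called genes had groups without overlap. Groups did not overlap at 16.7% of all genes in WT over mock, 15.7% in A384T over mock and 7.46% in A384T over WT, the last below the 10% expected by chance for 3 arrays against 3. They did not overlap at 11.5% in R397W over mock, 24.7% in R397W over WT and 23.6% in R397W over A384T (20% by chance for 3 against 2). These levels by chance assume arrays that vary independently. Differences shared by arrays of the same number, treated below, can make groups overlap more often. A share below such a level therefore does not show that 2 groups are alike.

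The array numbers in the titles may pair arrays across groups. The deviations of arrays from their group means correlated across genes at 0.107 to 0.718 in all 15 pairs of arrays with the same number (median 0.497), against a median of -0.362 in 30 pairs with different numbers. Deviations cancel within a group, so positive values at the same number force negative ones elsewhere. The negative median is thus no separate evidence of pairing. For the same reason, a difference shared by the arrays numbered 1 alone would give positive values among numbers 2 and 3, equal or not. In R397W, with 2 arrays, the deviations mirror each other. As every pair was above 0.1, the numbers were taken to pair the arrays, by the data and not by a label. Number 1 alone could meet this rule, so it does not show pairing of numbers 2 and 3. Pairs numbered 1 lay at 0.575 to 0.718, but numbers 2 and 3 were less clear. A384T 2 correlated at 0.284 with mock 3 and 0.273 with WT 3, against 0.107 with mock 2 and 0.179 with WT 2. A384T 3 correlated at 0.207 with mock 2 and 0.305 with mock 3. Between mock and WT, numbers 2 and 3 were at 0.489 and 0.555 when equal, and at -0.048 and -0.017 when not. The fit with the array number as a block (5 residual degrees of freedom, median residual standard deviation 0.157) rests on these less clear numbers as well. It is given where it changes the call of a list and where it changes the total count of a contrast by over 1.5 times. For single genes and counts of list members it is given in part. No array was a copy of another.

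The change in a mutant form per unit of the WT change was estimated as a slope over all genes after the noise covariance was subtracted, with a jackknife over arrays. The steps were tested on simulated data with the spread of these arrays and 200 changed genes per run. Without the block, 3.31% of genes changed by 0.5, 56.8% of genes changed by 1 and 92.6% of genes changed by 2 were recovered in WT over mock; for A384T over WT these were 3.54%, 58.7% and 94.5%. A list of 30 genes shifted by 0.5 was called in 5 of 5 runs of each contrast. Its genes were drawn at random with noise independent between genes. The estimated correlation was 0.703 for the real cell cycle list and 0.77 for glycolysis, so these runs do not test such lists. Alternatives tried were the mean of all probe sets of a gene, centring of each array on its median, array weights, other priors of eBayes, only the compared groups in the fit, the block, a 2-fold minimum, an estimated list correlation and leaving out each array; some more were added after the data were seen.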

Results

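Gene expression was measured in mouse CD4 T cells that carried FoxP3, a mutant form of FoxP3, or an empty vector. FoxP3 is the forkhead transcription factor that specifies regulatory T cells (Treg cells), and loss of its function causes IPEX, a severe autoimmune disease. The substitutions A384T and R397W lie in the forkhead domain, the part of the protein that binds DNA, and both are known from IPEX. Naive CD4 T cells of BALB/cA mice were activated, infected with retrovirus that also encoded green fluorescent protein (GFP), and sorted for high GFP on day 7. There were 3 arrays of mock-transduced cells, 3 of cells with wild-type (WT) FoxP3, 3 of cells with A384T FoxP3 and 2 of cells with R397W FoxP3. Each value was a log2 difference from the median of the 3 mock arrays at the same probe set, so that changes between groups could be read but expression levels could not. The median over all probe sets lay between -0.016 and 0.0022 on every array. The number of arrays limits the precision, with a median standard error (SE) of 0.158 between groups of 3 and 0.176 where R397W was compared. Changes below are log2 differences ± SE from limma with all 11 arrays in the fit, and p-values are adjusted by Benjamini-Hochberg over 18193 genes.

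The comparison of WT FoxP3 with mock transduction asked which genes FoxP3 by itself changes in activated CD4 T cells. The largest rise was that of Gpr83, a G protein-coupled receptor typical of Treg cells, which was 75.5-fold higher with WT FoxP3 (6.24 ± 0.22, adjusted p = 1.16e-06). Other Treg surface genes rose with it, among them Il2ra, the alpha chain of the IL-2 receptor (2.11 ± 0.15, adjusted p = 6.5e-05), Ctla4, an inhibitory receptor that binds CD80 and CD86 (1.75 ± 0.20, adjusted p = 0.000902), and Izumo1r, also called folate receptor 4 (3.57 ± 0.17). Lta, the cytokine lymphotoxin alpha, was 32.7-fold higher (5.03 ± 0.54). Among the genes that fell most, Itga7, a laminin-binding integrin chain, was 13.9-fold lower (-3.80 ± 0.51) and Cxcr6, the receptor for the chemokine CXCL16, was 9.49-fold lower (-3.25 ± 0.27).

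The other large rises with WT FoxP3 were those of Cyp4f18, a cytochrome P450 that acts on leukotriene B4 (5.40 ± 0.29), Drc1, a part of the dynein regulatory complex of cilia (4.88 ± 0.23), and Gzmc, a granzyme (4.63 ± 0.22). Next came Tgm2, a protein-crosslinking transglutaminase (4.56 ± 0.39), Tnfrsf9, the costimulatory receptor 4-1BB (4.13 ± 0.30), Hbegf, an EGF-like growth factor (3.86 ± 0.43), Socs2, an inhibitor of cytokine signalling (3.85 ± 0.41), and Trib1, a pseudokinase (3.84 ± 0.29). The other large falls were those of Fcgrt, the heavy chain of the neonatal Fc receptor (-3.80 ± 0.36), Atp8b4, a P-type ATPase of the flippase family (-3.73 ± 0.35), and Pik3ap1, an adaptor of phosphoinositide 3-kinase (-3.49 ± 0.48). They were followed by Klrd1, the NK receptor chain CD94 (-3.28 ± 0.29), Nebl, an actin-binding protein (-3.13 ± 0.24), Tbc1d4, a Rab GTPase-activating protein (-3.04 ± 0.35), Lypd6b (-2.89 ± 0.17) and St3gal6, a sialyltransferase (-2.87 ± 0.32). The transcription factor Irf4, which Treg cells use together with FoxP3, rose by 2.24 ± 0.41 (adjusted p = 0.0138). Its partner Batf was at 0.57 ± 0.32 (adjusted p = 0.567, and 0.017 with the array number as a block). Il2, Ifng and Il7r did not pass the test, at -0.16 ± 0.12, -0.21 ± 0.13 and -0.47 ± 0.34. The Foxp3 probe set itself was at 0.04 ± 0.15 (adjusted p = 0.977), and whether its probes lie in the transduced sequence is not given in the sources used here.

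Of the gene lists, genes known to be higher in Treg cells stood out most with WT FoxP3. Of 28 measured, 14 rose and 0 fell (18 and 1 adjusted over the list alone), the median difference was 1.30, and the list was higher as a set (camera, adjusted p = 1.1e-25, and adjusted p = 0.00728 with an estimated correlation). Targets of IL-2 and STAT5 signalling followed, with 11 of 21 higher and 0 lower (14 and 1 adjusted over the list alone). They included Gzmb (3.30 ± 0.67) and Cish, a feedback inhibitor that STAT5 induces (8.03-fold higher, SE of the log2 difference 0.19), and the set test gave an adjusted p = 1.96e-19 (adjusted p = 0.0646 with an estimated correlation). AP-1, BATF and IRF factors were higher as a set, with 3 of 19 called higher (4 adjusted over the list alone), among them Maff (2.34 ± 0.38) and Jdp2 (0.91 ± 0.16). With the array number as a block, 7 were called higher and 0 lower. The adjusted p of the set test was 0.00897 (adjusted p = 0.23 with an estimated correlation). Inhibitory receptors and ligands were also higher as a set, with 4 of 17 higher and 1 lower by either adjustment (adjusted p = 0.00926, and adjusted p = 0.128 with an estimated correlation). Those that rose were Nt5e, the ecto-enzyme CD73 that makes adenosine (3.48 ± 0.25), Cd274 and Pdcd1lg2, the ligands of PD-1 (1.99 ± 0.33 and 1.82 ± 0.24), and Ctla4. Early genes of T cell receptor (TCR) stimulation had 4 of 19 higher and 1 lower by either adjustment, among them Cd69 (2.30 ± 0.41) and Nfkbia, the inhibitor of NF-kappaB (1.21 ± 0.24), with an adjusted p = 0.00192 (adjusted p = 0.23 with an estimated correlation).

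Other lists moved down with WT FoxP3. Interferon-stimulated genes were lower as a set, with 6 of 25 lower and 2 higher (10 and 2 adjusted over the list alone; adjusted p = 3.73e-05, and adjusted p = 0.23 with an estimated correlation). With the array number as a block, 10 of the 25 were called lower and 2 higher. The antiviral genes Ifit1 and Oas3 and the transcription factor Irf7 fell by 2.07, 1.86 and 1.74, whereas Gbp3, a guanylate-binding protein, was 8.03-fold higher (SE of the log2 difference 0.24). Genes of type 1 helper (Th1) cells were lower as a set, with 4 of 14 lower by either adjustment (adjusted p = 0.0147, adjusted p = 0.23 with an estimated correlation, and 0.0936 with the array number as a block). The 4 were both chains of the IL-18 receptor, Il18rap (-2.08 ± 0.23) and Il18r1 (-1.62 ± 0.24), the death ligand Fasl (-1.43 ± 0.20) and the chemokine Ccl5 (-0.57 ± 0.12). Glycolysis genes were lower as a set with 0 of 17 called (1 lower adjusted over the list alone; adjusted p = 0.0258, and adjusted p = 0.656 with an estimated correlation). With the array number as a block, 1 glycolysis gene was called higher and 5 lower. Aldoa and Aldoc, which encode aldolases, were at -1.26 (adjusted p = 0.438, blocked 0.00184) and -1.25 (adjusted p = 0.0608, blocked 0.00157). The glycolysis call was lost without mock 2 (adjusted p = 0.54), mock 3 (0.187) or WT 1 (0.181). Cell cycle genes were higher as a set (median 0.79, adjusted p = 1.04e-07, and adjusted p = 0.463 with an estimated correlation), although Mcm5, a helicase subunit, was the 1 gene of 31 called (1.95 ± 0.42, adjusted p = 0.0311), against 14 with the array number as a block. These last lists also differed between arrays within groups. The median of the cell cycle list was higher on the array numbered 1 than on the other arrays of its group, by 0.164 for mock, 1.38 for WT, 1.02 for A384T and 0.415 for R397W, and 12 of 17 glycolysis genes were lower on the arrays numbered 1.

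**Figure D1:**
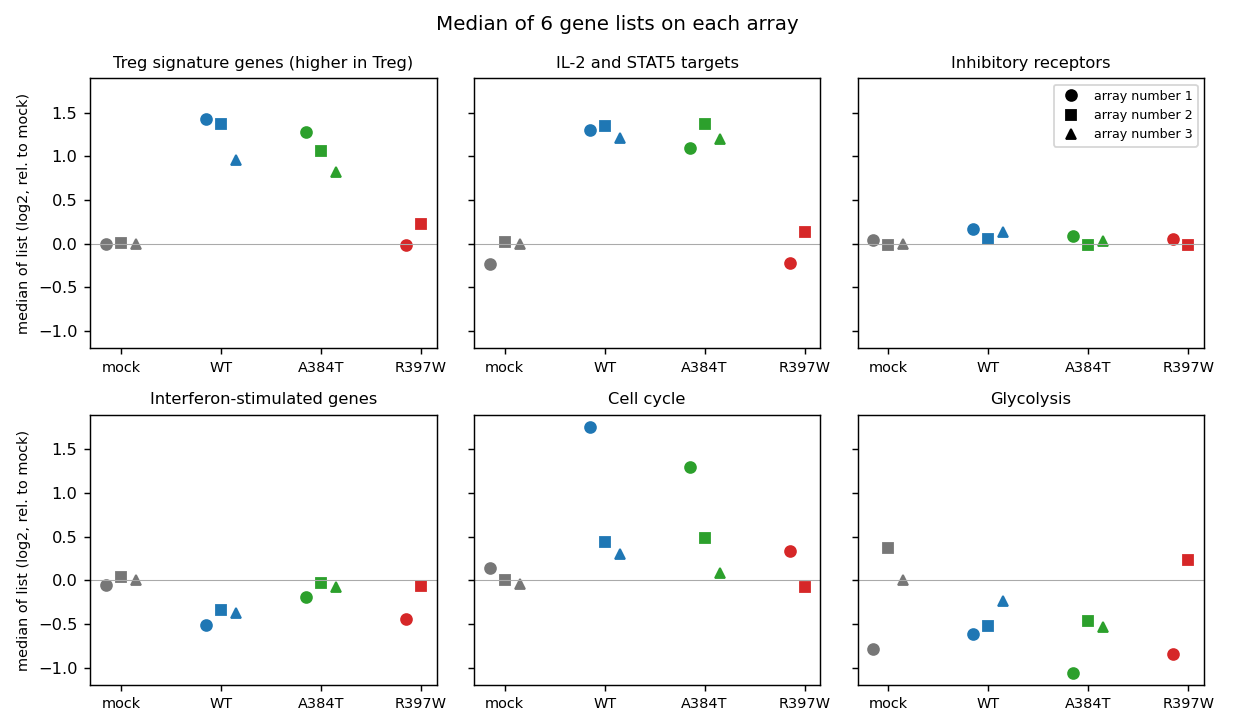
Median log2 difference from mock of 6 gene lists on each array (vertical axis), by group (horizontal axis), with the marker shape giving the array number. The Treg and IL-2/STAT5 lists lay above 0.8 on all 6 WT and A384T arrays and below 0.3 on the mock and R397W arrays, and the cell cycle list was highest on the array numbered 1 of each group.

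The remaining T cell lists were not called in WT over mock. Genes known to be lower in Treg cells had 4 of 16 lower and 2 higher (adjusted p = 0.0703, 0.0401 lower with the block, and 0.349 with an estimated correlation and no block), with Pde3b (-1.63 ± 0.18) and the phosphatase Ptpn22 (-1.35 ± 0.13) among those that fell, and Tnf (3.06 ± 0.44) and Id3 (2.24 ± 0.22) rising. Tissue Treg genes had 7 of 28 higher and 3 lower (adjusted p = 0.0703, 0.0281 higher with the block, and 0.455 with an estimated correlation and no block), with Itgae, the integrin chain CD103, 8.02-fold higher (SE of the log2 difference 0.26). Oxidative phosphorylation genes had 0 of 20 higher and 1 lower, Ndufb8 (-0.47 ± 0.10), with an adjusted p = 0.0703, 0.049 higher with the block, and 0.323 with an estimated correlation and no block. Effector cytokines had 2 of 25 higher and 4 lower, with Il4 down by 1.98, and their median (-0.12) and mean (0.12) differed in sign (adjusted p = 0.168). The lists of Th2 genes (0.482), Th17 genes (0.84), chemokine and homing receptors (0.135), cytotoxic genes (0.717), cholesterol synthesis (0.188), TCR signalling components (0.0853), naive and memory T cell genes (0.887), p53 targets (0.0853) and stress response genes (0.866) had the adjusted p-values given after each name. Among their called genes were the chemokine receptors Ccr4 (1.30 ± 0.23) and Ccr2 (-1.35 ± 0.27) and the stress genes Xbp1 (1.84 ± 0.19) and Hspa8 (-0.91 ± 0.18). Plcg1 of the TCR pathway (-0.49 ± 0.11), Igfbp4 of the naive list (-1.30 ± 0.23) and the stress gene Herpud1 (0.76 ± 0.16) were called as well.

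Markers of other cell types were not called as sets in WT over mock, at an adjusted p = 0.322 for B cells, 0.135 for MHC class II and antigen presentation and 0.374 for macrophages and dendritic cells. The values were 0.557 for granulocytes and mast cells, 0.575 for CD8, NK and gamma-delta T cells, 0.686 for erythroid cells and platelets, and 0.804 for fibroblasts and endothelium. Called genes among them were H2-Oa (-1.01 ± 0.15), H2-DMb2 (0.95 ± 0.20), Cd86 (0.93 ± 0.18), the Fc receptor gene Fcgr3 (-1.75 ± 0.21) and the collagen gene Col1a2 (2.33 ± 0.51). In all, 659 genes differed between WT and mock, 363 higher and 296 lower. With the array number as a block there were 1849, 975 higher and 874 lower, which held all 659. With a trend and robust prior there were 333, 207 higher and 126 lower. The count was 402 without WT 2, 405 without WT 1, 409 without mock 2 and 393 without the arrays numbered 1. The Th1 call was lost without the arrays numbered 1 (adjusted p = 0.0532) and the inhibitory receptor call with the mean of all probe sets (0.0522). Of 61 called genes chosen by the naming rule, 44 were called in every fit without 1 array, all 20 of the largest changes among them. Mcm5 was lost in 6 of the 11 fits (highest adjusted p = 0.115), Col1a2 in 7 (0.123), H2-DMb2 in 5 (0.122) and Irf4 in 2 (0.0568). The others lost in at least 1 fit were Ccl5, Ccr2, Ccr4, Cd69, Cd86, Gzmb, Herpud1, Hspa8, Igfbp4, Jdp2, Ndufb8, Nfkbia and Plcg1.

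**Figure D2:**
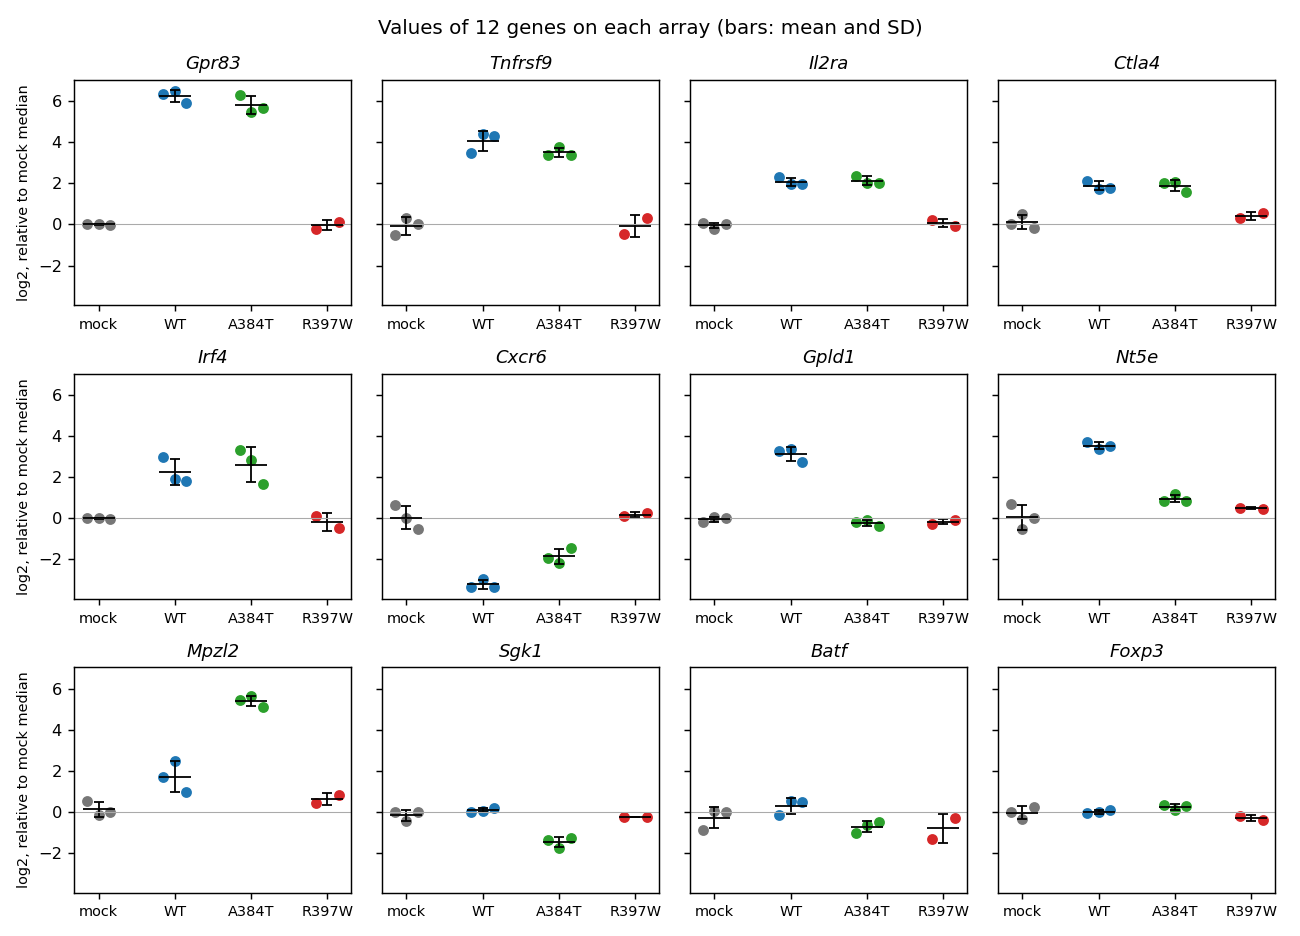
Log2 values relative to the mock median (vertical axis) of 12 genes on each array, by group (horizontal axis), with bars for the mean and standard deviation. Gpr83, Tnfrsf9, Il2ra, Ctla4 and Irf4 were high on the WT and A384T arrays and near 0 on the mock and R397W arrays, whereas Gpld1 and Nt5e were high with WT FoxP3 and Mpzl2 was highest with A384T.

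The comparison of A384T with mock asked which genes this mutant form changes. Gpr83 was 55.8-fold higher than in mock cells (5.80 ± 0.22, adjusted p = 2.38e-06) and Lta was 51.3-fold higher (5.68 ± 0.54). Il2ra (2.17 ± 0.15), Ctla4 (1.76 ± 0.20) and Irf4 (2.61 ± 0.41) rose. Mpzl2, an adhesion molecule of the immunoglobulin family, was 38.1-fold higher (5.25 ± 0.34).

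Tgm2 (5.04 ± 0.39) and Drc1 (4.84 ± 0.23) completed the 5 largest rises with A384T. The 5 largest falls were those of Fcgrt (-3.89 ± 0.36), Atp8b4 (-3.70 ± 0.35), Epas1, the hypoxia-inducible factor HIF-2alpha (-3.28 ± 0.22), Rnf144a, a ubiquitin ligase (-3.28 ± 0.32), and Pik3ap1 (-3.27 ± 0.48). Of the Treg list, 14 of 28 genes rose and 0 fell (18 and 2 adjusted over the list alone; adjusted p = 3.41e-16, and adjusted p = 0.031 with an estimated correlation). Of the IL-2 and STAT5 targets, 10 of 21 rose and 0 fell (13 and 1 adjusted over the list alone; adjusted p = 1.61e-16, and adjusted p = 0.0941 with an estimated correlation). AP-1, BATF and IRF factors were higher as a set, with 3 of 19 higher (4 adjusted over the list alone; adjusted p = 0.0139, and adjusted p = 0.362 with an estimated correlation). Cell cycle genes were higher as a set (adjusted p = 6.01e-06) with 1 of 31 called, Mcm5, by either adjustment, and 9 higher and 1 lower with the array number as a block. Glycolysis genes were lower as a set (adjusted p = 0.0178) with 0 of 17 called by either adjustment, and 0 higher and 5 lower with the block. Both of these calls had an adjusted p = 0.826 with an estimated correlation, and the differences between arrays within groups given above apply to them. Cholesterol synthesis genes had 0 of 17 called (adjusted p = 0.0763, 0.0466 lower with the block, and 0.826 with an estimated correlation and no block), with Stard4 at -0.69 (adjusted p = 0.0742, blocked 0.0114).

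Interferon-stimulated genes had 2 of 25 higher and 3 lower with A384T and were not called as a set (adjusted p = 0.391). Among chemokine receptors, Cxcr3, a receptor of Th1 cells, rose by 2.01 ± 0.37 (adjusted p = 0.0157) and Cxcr6 fell by 1.89. Batf was at -0.44 ± 0.32 (adjusted p = 0.694) and Foxp3 at 0.27 ± 0.15 (adjusted p = 0.559). Il7r, the IL-7 receptor, was at -0.91 ± 0.34 (adjusted p = 0.268, and 0.00453 with the block), and Il2 and Ifng were at -0.26 ± 0.12 and -0.11 ± 0.13. No list of other cell types was called, and the macrophage list held 2 called genes, Fcgr3 (-2.53 ± 0.21) and Adgre1 (-1.13 ± 0.20). In all, 577 genes differed between A384T and mock, 326 higher and 251 lower, against 1839 with the array number as a block, which held all 577. With a trend and robust prior there were 245, 167 higher and 78 lower, and with only these 2 groups in the fit 343. The count was 367, 366 and 371 without mock 1, 2 or 3, 345 and 357 without A384T 1 or 2, and 259 without the arrays numbered 1, and the glycolysis call was lost without mock 2 (adjusted p = 0.623), mock 3 (0.173) or A384T 1 (0.219). Of 52 called genes chosen by the naming rule, 32 were called in every fit without 1 array, and of those named here Mcm5 was lost in 8 of the 11 fits (highest adjusted p = 0.143), Cxcr3 in 3 (0.072) and Adgre1 in 1 (0.053).

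The genes that WT FoxP3 changed were followed in the A384T cells. Of the 363 genes that rose with WT FoxP3, 230 also rose with A384T (6.50 for independent lists of these sizes), and of the 296 that fell, 186 also fell (4.08 for independent lists). Part of this excess may come from the shared mock arrays, which at 3 are too few to split. The median difference of the 363 genes was 1.22 with WT FoxP3 and 1.08 with A384T, and that of the 296 genes was -1.05 and -0.86. These genes were picked on the same WT arrays, which favours larger WT values, so the medians do not show a weaker effect of A384T. Across all genes, which are not independent replicates, the A384T difference rose by 0.899 per unit of the WT difference with the array number as a block (jackknife SE 0.071) and by 1.02 without it (jackknife SE 0.15), after the noise was subtracted. On simulated data with differences between array numbers, the unblocked slope read 1.38 where the true slope was 1 and the blocked slope read 1.00. The correlation of the WT and A384T differences was 0.862 and the covariance 0.137, against 0.50 and 0.028 for simulated unchanged groups that share the mock arrays, and 0.502 and 0.0124 with differences between array numbers in the simulation.

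The comparison of R397W with mock asked which genes this mutant form changes. No gene passed the test over all genes, and adjusted over the list alone 1 of 25 effector cytokines was lower. The Treg genes that rose with WT FoxP3 lay near their mock values: Il2ra was at 0.12 (95% confidence interval -0.26 to 0.49), Ctla4 at 0.30 (-0.20 to 0.81) and Irf4 at -0.19 (-1.21 to 0.83). List genes whose intervals left out 0 included Csf1, a macrophage growth factor (-0.97, interval -1.44 to -0.51), the antiviral gene Ifit1 (-1.10, -1.81 to -0.39) and Ecm1, a Treg list gene (0.90, 0.18 to 1.63), each with an adjusted p = 1.00.

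The T cell genes Batf (-0.51, -1.32 to 0.29), Il7r (0.25, -0.60 to 1.10), Ifng (-0.04, -0.36 to 0.29) and Il2 (0.31, 0.01 to 0.60) were not called, and neither was Foxp3 (-0.27, -0.65 to 0.12). Gzmb, an IL-2 target, was at 1.46 (-0.20 to 3.12). Interferon-stimulated genes were the 1 list called, lower as a set with 0 of 25 genes called by either adjustment and a median of -0.23 (adjusted p = 1.11e-06, and adjusted p = 0.506 with an estimated correlation). The call was lost without R397W 1 (adjusted p = 0.51) and without the arrays numbered 1 (0.158). With the array number as a block, the Th1 list (adjusted p = 0.102, blocked 0.00152) and the Th17 list (0.124, blocked 0.00863) were lower as well, with 0 members called in either and an adjusted p = 0.588 and 0.506 with an estimated correlation and no block. The Treg list (0.128) and the IL-2 and STAT5 list (0.793) were not called. limma called 0 of 18193 genes between R397W and mock, 306 had an unadjusted p under 0.05, and 0 were called with the array number as a block. In simulated data of this comparison, 43.5% of genes changed by 1 log2 unit and 85.5% of those changed by 2 were recovered. These rates hold for 200 changed genes per run. With fewer changed genes the adjustment is stricter and fewer would be recovered.

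**Figure D3:**
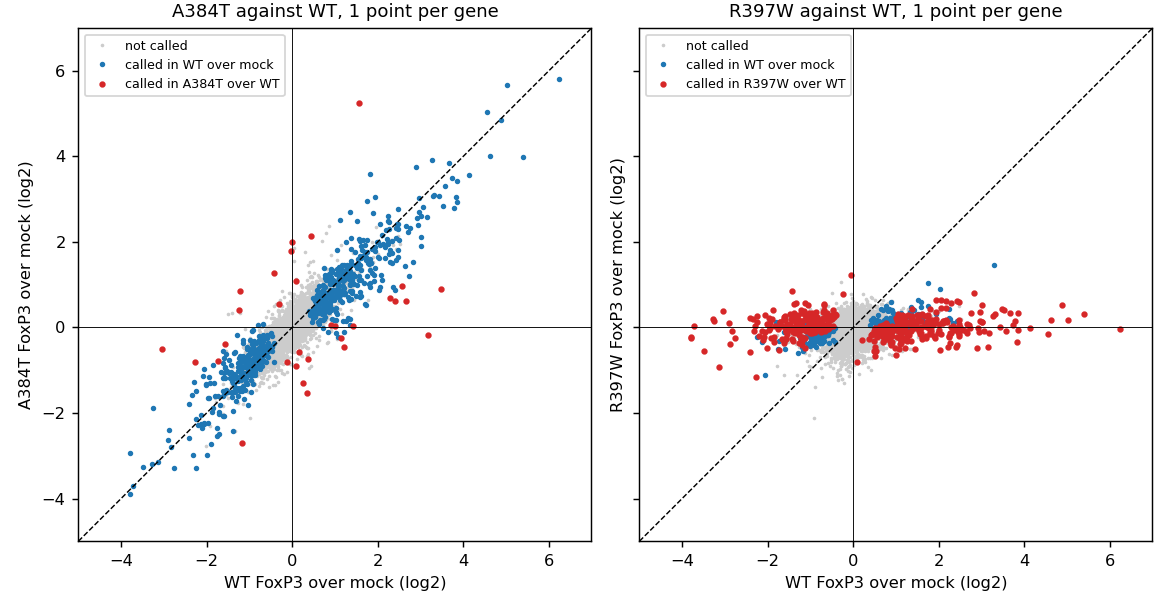
Log2 difference of A384T from mock (left) and of R397W from mock (right) on the vertical axes against that of WT FoxP3 from mock on the horizontal axes, with 1 point per gene, genes called in WT over mock in blue and genes called between the mutant form and WT in red. The A384T points lie along the dashed line of equal differences, with 31 genes in red, and the R397W points lie near 0 across the range of WT differences, with 459 genes in red.

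The comparison of A384T with WT FoxP3 asked where the mutant form differs from WT. Gpld1, a phospholipase that releases GPI-anchored proteins, was 10.2-fold lower with A384T (-3.35 ± 0.17, adjusted p = 3.26e-05). Over mock it was at 3.17 with WT FoxP3 and at -0.17 with A384T. Nt5e (CD73) was 5.96-fold lower (-2.57 ± 0.25, adjusted p = 0.00526). Mpzl2 was 12.8-fold higher (3.68 ± 0.34, adjusted p = 0.00377). Il2ra (0.06 ± 0.15), Ctla4 (0.006 ± 0.20) and Irf4 (0.37 ± 0.41) did not pass the test between these groups.

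Genes lower with A384T than with WT FoxP3 also included B3galnt1, a glycosyltransferase (-2.04 ± 0.27), Metrnl, a secreted protein (-1.88 ± 0.23), and Cyp11a1, the enzyme that makes pregnenolone from cholesterol (-1.77 ± 0.26). Lower too were Pglyrp1, a peptidoglycan recognition protein (-1.68 ± 0.20), Ell2, a transcription elongation factor (-1.60 ± 0.19), Adamtsl4 (-1.60 ± 0.24), Sgk1, a serum- and glucocorticoid-induced kinase (-1.55 ± 0.16), and Map6, a microtubule-stabilizing protein (-1.52 ± 0.22). Genes higher with A384T were Tbc1d4 (2.54 ± 0.35), AA467197 (2.07 ± 0.30), Asb2, a ubiquitin ligase subunit (2.00 ± 0.31), and Car2, a carbonic anhydrase (1.82 ± 0.21). They were followed by Ctla2a, a cysteine protease inhibitor (1.70 ± 0.24), Synpo, an actin-associated protein (1.69 ± 0.21), P2ry14, the UDP-glucose receptor (1.65 ± 0.15), Rtp4, an interferon-induced gene (1.48 ± 0.21), and 4930486L24Rik (1.19 ± 0.18). Of the 31 genes, 18 were called in WT over mock, and 12 were called in A384T over mock and not in WT over mock. Sgk1, for example, was at 0.24 with WT FoxP3 and at -1.30 with A384T over mock. Foxp3 was at 0.23 ± 0.15 and Il2, Ifng and Il7r at -0.11 ± 0.12, 0.09 ± 0.13 and -0.44 ± 0.34. Batf was at -1.01 ± 0.32 (adjusted p = 0.723, and 0.00439 with the array number as a block).

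**Figure D4:**
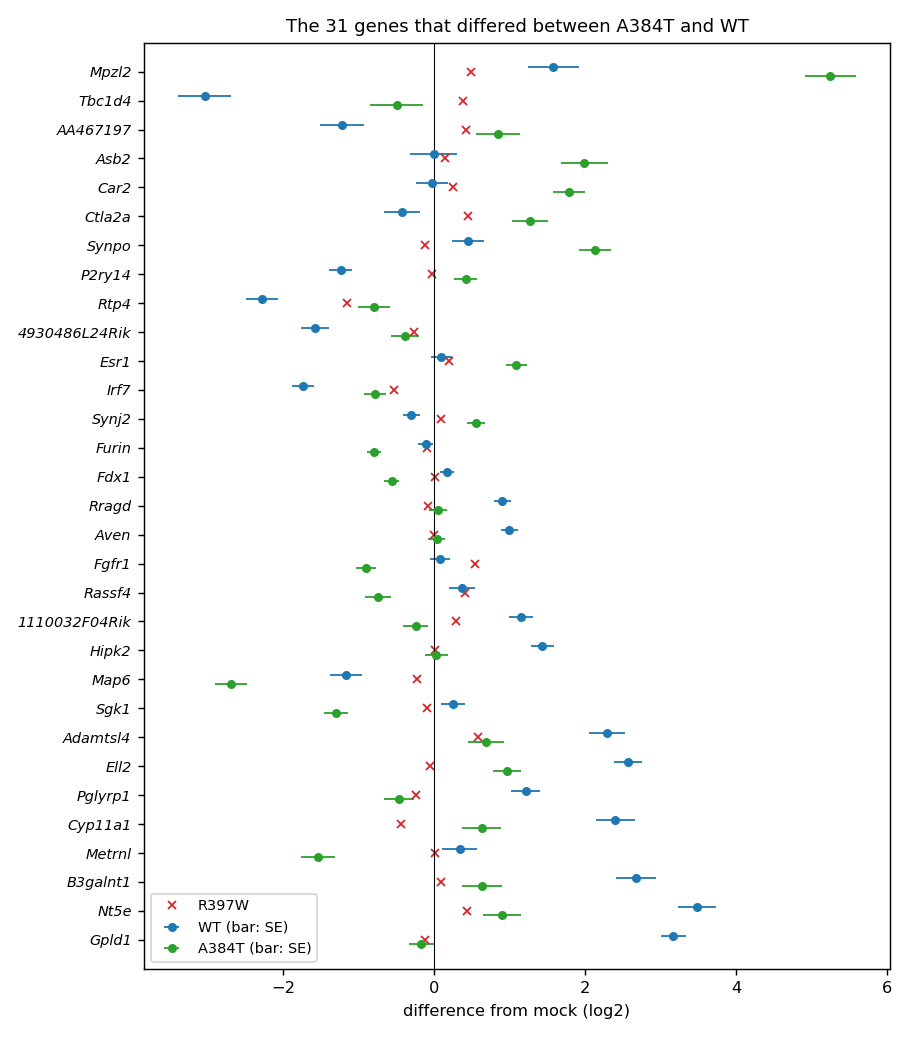
Log2 difference from mock (horizontal axis) with WT FoxP3, A384T and R397W of the 31 genes that differed between A384T and WT (vertical axis), with bars for the standard error of the WT and A384T differences. Gpld1 and Nt5e were highest with WT FoxP3, with Nt5e at 0.90 ± 0.25 with A384T, and Asb2, Car2, Sgk1 and Metrnl lay farther from 0 with A384T than with the other forms.

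Of the Treg list, 1 of 28 genes, Nt5e, fell from WT to A384T (5 adjusted over the list alone), and the list was lower as a set (median -0.34, adjusted p = 6.79e-07, and adjusted p = 0.104 with an estimated correlation). With the array number as a block, 5 Treg list genes and 4 inhibitory receptors were lower, and 0 higher in either list. Inhibitory receptors were lower as a set, again with Nt5e as the 1 called of 17 (5 adjusted over the list alone; adjusted p = 0.00142, and adjusted p = 0.0741 with an estimated correlation). Interferon-stimulated genes were higher as a set, with Irf7 (0.96 ± 0.15) as the 1 called of 25 (6 higher and 1 lower adjusted over the list alone; adjusted p = 4.57e-07, and adjusted p = 0.208 with an estimated correlation). The Irf7 call was lost in each of the 11 fits without 1 array. Targets of p53 were lower as a set with 0 of 17 called by either adjustment (adjusted p = 0.00142, and adjusted p = 0.0741 with an estimated correlation). Th1 genes were higher as a set with 0 of 14 called (3 adjusted over the list alone; adjusted p = 0.0102, and adjusted p = 0.208 with an estimated correlation), with Cxcr3 at 1.32 ± 0.37 (adjusted p = 0.526, and 0.00297 with the block). Tissue Treg genes were lower as a set with 0 of 28 called (2 higher and 2 lower adjusted over the list alone; adjusted p = 0.0142, and adjusted p = 0.342 with an estimated correlation). Early TCR genes were lower as a set with 0 of 19 called by either adjustment (adjusted p = 0.0354, and adjusted p = 0.366 with an estimated correlation). The list of genes lower in Treg cells (0.055, 0.0341 higher with the block, and 0.342 with an estimated correlation and no block) and the IL-2 and STAT5 list (0.0574, 0.00873 lower with the block, and 0.637 with an estimated correlation and no block) were called only with the block, and no list of other cell types was called.

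In all, 31 genes differed between A384T and WT, 13 higher and 18 lower, against 159 with the array number as a block, 75 higher and 84 lower, which held all 31. The count was 14, 5 and 13 without WT 1, 2 or 3, 14 and 17 without A384T 2 or 3, 18 without either R397W array, 12 with only these 2 groups in the fit and 3 without the arrays numbered 1. Of the 20 genes with the largest changes, 5 were called in every fit without 1 array, namely Gpld1, Nt5e, Mpzl2, Ell2 and P2ry14. Of the list calls, Th1 was lost without A384T 2 (adjusted p = 0.155) and without the arrays numbered 1 (0.136), tissue Treg without WT 2 (0.0525) and early TCR without WT 2 (0.148), WT 3 (0.059) or A384T 3 (0.363). With the mean of all probe sets, Th1 and early TCR were both at 0.0646.

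The comparison of R397W with WT FoxP3 asked where this mutant form differs from WT. Gpr83 was 77.5-fold lower with R397W (-6.28 ± 0.25, adjusted p = 3.3e-06), and Il2ra (3.99-fold, SE of the log2 difference 0.17), Ctla4 (-1.45 ± 0.23), Irf4 (-2.43 ± 0.46) and Tnfrsf9 (-4.14 ± 0.34) were lower too. Cxcr6 was 10.5-fold higher with R397W (3.40 ± 0.31), as were Atp8b4 (3.76 ± 0.39) and Itga7 (3.59 ± 0.57). Of the 363 genes that rose with WT FoxP3, 236 were lower with R397W than with WT, 0 were higher and 127 were not called. Of the 296 that fell, 187 were higher with R397W, 0 were lower and 109 were not called. Both comparisons use the same WT arrays, which by itself favours these directions, and the size of that effect was not computed.

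Other large differences were lower values with R397W of Cyp4f18 (-5.10 ± 0.32), Lta (-4.86 ± 0.61), Tgm2 (-4.72 ± 0.44), Gzmc (-4.46 ± 0.25), Drc1 (-4.35 ± 0.26), Trib1 (-4.18 ± 0.33), Hbegf (-3.91 ± 0.48) and Gldc, a subunit of the glycine cleavage system (-3.68 ± 0.44). Higher with R397W were Fcgrt (3.54 ± 0.40), Klrd1 (3.48 ± 0.32), Tbc1d4 (3.42 ± 0.39), Lypd6b (3.01 ± 0.19), Pik3ap1 (2.95 ± 0.54), Cyp2s1, a cytochrome P450 (2.75 ± 0.21), and Alox5ap, which activates 5-lipoxygenase (2.64 ± 0.31). Of the Treg list, 11 of 28 genes were lower and 0 higher (17 and 0 adjusted over the list alone; adjusted p = 2.24e-23, and adjusted p = 0.00975 with an estimated correlation). Of the IL-2 and STAT5 targets, 9 of 21 were lower and 0 higher (12 and 0 adjusted over the list alone), among them Il2rb, the beta chain of the IL-2 receptor (-2.48 ± 0.23). Their set test gave an adjusted p = 6.51e-21 (adjusted p = 0.0531 with an estimated correlation). With the array number as a block, 17 Treg list genes, 15 of these targets and 7 AP-1, BATF and IRF factors were lower, and 0 higher. AP-1, BATF and IRF factors (3 of 19 lower, 4 adjusted over the list alone; adjusted p = 0.000604, and adjusted p = 0.136 with an estimated correlation) were lower as a set. So were early TCR genes (4 of 19 lower, 4 lower and 1 higher adjusted over the list alone; adjusted p = 0.00199, and adjusted p = 0.239 with an estimated correlation). Tissue Treg genes were lower as a set, with 6 of 28 lower and 2 higher (7 and 2 adjusted over the list alone; adjusted p = 0.00256, and adjusted p = 0.239 with an estimated correlation). Inhibitory receptors were lower as a set, with 4 of 17 lower (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.0424, adjusted p = 0.202 with an estimated correlation, and 0.0869 with the array number as a block). Cell cycle genes were lower as a set with 0 of 31 called by either adjustment (adjusted p = 6.11e-06, and adjusted p = 0.55 with an estimated correlation) and 13 called with the block, and the differences between arrays within groups given above apply to them.

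Batf was at -1.08 ± 0.36 between R397W and WT (adjusted p = 0.224, and 0.00231 with the block), Il7r at 0.72 ± 0.38 (0.579, and 0.02 with the block), and Il2, Ifng and Foxp3 at 0.46 ± 0.13, 0.17 ± 0.14 and -0.30 ± 0.17. Interferon-stimulated genes were not called as a set (adjusted p = 0.211), with Gbp3 lower (-2.48 ± 0.27) and Oas3 higher (1.63 ± 0.27). In all, 459 genes differed, 207 higher and 252 lower, against 1460 with the array number as a block (657 and 803), which held all 459 with the same sign. A trend and robust prior gave 224, 80 higher and 144 lower. The count was 296 and 272 without WT 1 or 2, 168 and 217 without R397W 1 or 2, 203 with only these 2 groups in the fit and 168 without the arrays numbered 1. Of 55 called genes chosen by the naming rule, 34 were called in every fit without 1 array. Irf4 was lost without WT 1, WT 2, R397W 1 or R397W 2 (highest adjusted p = 0.171), Ctla4 without R397W 1 (0.0915) and Oas3 in 1 fit (0.104). Itga7 was not called without R397W 2, Pik3ap1 without WT 2, WT 3 or R397W 2, the early TCR list without R397W 1 (adjusted p = 0.142) and the cell cycle list without WT 1 (0.0593). The inhibitory receptor list was not called without mock 3 (0.0558), WT 1 (0.0546), WT 3 (0.0859), A384T 1 (0.054), A384T 2 (0.05), R397W 2 (0.123) or the arrays numbered 1 (0.0509), nor with the mean of all probe sets (0.0893).

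Over all genes, the R397W difference from mock changed by -0.0281 per unit of the WT difference with the array number as a block (jackknife SE 0.091) and by -0.126 without it (jackknife SE 0.19). On simulated data with differences between array numbers, the unblocked slope read -0.386 and the blocked slope -0.0051 where the true slope was 0. The correlation of the WT and R397W differences across genes was 0.199 and the covariance 0.0145, against 0.448 and 0.028 for simulated unchanged groups that share the mock arrays. With differences between array numbers in the simulation these values were 0.404 and 0.0124, so the observed covariance lay below the simulated value without number effects and above it with them. In the fit with the array number as a block, the observed covariance was 0.0084 and that of the noise 0.0123. At the 363 genes that rose with WT FoxP3 the median R397W difference from mock was 0.05, and at the 296 that fell it was -0.05.

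The comparison of R397W with A384T asked where the mutant forms differ from each other. Gpr83 was 57.2-fold lower with R397W than with A384T (-5.84 ± 0.25, adjusted p = 6.75e-06), and Lta (-5.51 ± 0.61), Tgm2 (-5.21 ± 0.44), Mpzl2 (-4.76 ± 0.37) and Drc1 (-4.32 ± 0.26) were lower as well. Atp8b4 (3.74 ± 0.39), Fcgrt (3.64 ± 0.40), Epas1 (3.55 ± 0.24), Klrd1 (3.39 ± 0.32) and Tmem86b, which acts on lysoplasmalogens (3.06 ± 0.34), were higher with R397W. Il2ra (-2.06 ± 0.17), Ctla4 (-1.45 ± 0.23), Irf4 (-2.80 ± 0.46) and Cxcr3 (-2.20 ± 0.41) were lower.

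Of the Treg list, 11 of 28 genes were lower with R397W than with A384T and 0 higher (15 and 1 adjusted over the list alone; adjusted p = 4.71e-13, and adjusted p = 0.058 with an estimated correlation). Of the IL-2 and STAT5 targets, 9 of 21 were lower and 0 higher (12 and 0 adjusted over the list alone; adjusted p = 1.24e-17, and adjusted p = 0.0798 with an estimated correlation). AP-1, BATF and IRF factors were lower as a set, with 2 of 19 lower (3 adjusted over the list alone; adjusted p = 0.000536, and adjusted p = 0.132 with an estimated correlation). Cell cycle genes were lower as a set with 0 of 31 called by either adjustment (adjusted p = 0.00029, and adjusted p = 0.934 with an estimated correlation), 7 called with the block, and the differences between arrays within groups given above. Glycolysis genes had 0 of 17 called (adjusted p = 0.366, 0.0307 higher with the block, and 0.934 with an estimated correlation and no block). Il7r was at 1.16 ± 0.38 (adjusted p = 0.221, and 0.00186 with the block), Il2 at 0.57 ± 0.13 (0.0602, and 0.0341 with the block), and Batf, Ifng and Foxp3 at -0.07 ± 0.36, 0.08 ± 0.14 and -0.53 ± 0.17. Among markers of other cell types, Fcgr3 (2.50 ± 0.24) and Adgre1 (1.19 ± 0.22) were higher and the B cell gene Bank1 (-1.17 ± 0.23) was lower, with no such list called. In all, 413 genes differed, 173 higher and 240 lower, against 1460 with the array number as a block (639 and 821), which held all 413 with the same sign. A trend and robust prior gave 184, 63 higher and 121 lower. The count was 266 and 249 without A384T 1 or 2, 126 and 171 without R397W 1 or 2, 113 with only these 2 groups in the fit and 102 without the arrays numbered 1. The cell cycle call was lost without A384T 1 (adjusted p = 0.17) or R397W 2 (0.0517). Of 43 called genes chosen by the naming rule, 18 were called in every fit without 1 array, and of those named here Cxcr3 was lost in 4 of the 11 fits (highest adjusted p = 0.169), Adgre1 in 4 (0.172), Bank1 in 3 (0.172), Irf4 in 2 (0.113) and Ctla4 in 1 (0.0978).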

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

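The tests of the explanations weighed here were chosen only after the results had been seen, apart from the regrouping of the arrays, which was fixed before.

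Between A384T and WT FoxP3, 31 genes differed, a test of the difference between these forms. A form that acts as WT FoxP3 does, more weakly on every gene, would leave each A384T mean between mock and WT, but 17 of the 31 means lay outside that range by more than 2 SE, 12 past mock and 5 beyond WT. Where WT lay near mock, as at Asb2 (-0.0075) and Car2 (-0.026), the sign of a small difference set the side, not whether the mean lay outside. The 31 genes were also picked on these same arrays for a gap between A384T and WT, which favours means outside the range. The count of 17 therefore decides nothing by itself. Over mock, 12 of the 31 were called with A384T and not with WT, each in the direction in which it differed from WT. Mpzl2, called over mock with both forms, was at 5.25 with A384T and 1.58 with WT. At these genes the values argue against an action weaker on every gene. Of the 20 largest changes, 5 were called in every fit without 1 array, Mpzl2 among them. A weaker action on most genes stays open, as 12 of the 31 means lay between mock and WT within 1 SE. All 31 genes were called with the array number as a block, but this is no test of batches, because both groups hold the same 3 numbers and the block cannot move their difference; without the arrays numbered 1, 3 genes were called, 2 of them among the 31, with fewer arrays. A change in which genes the A384T form acts on stays open as a hypothesis, and so does a difference in the amount of FoxP3 protein with effects in both directions, which was not tested. Of the 10 splits of the 6 WT and A384T arrays into groups of 3, the real split called 31 genes and the highest other 0, with 1 split reaching the real count; 10 splits are too few for a share under 0.05.

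At 6 of the 31 genes (AA467197, P2ry14, Synj2, Fdx1, Sgk1 and Pglyrp1) all WT arrays lay on the opposite side of all mock arrays from all A384T arrays. None of the 6 was called over mock with both forms, so no gene was shown to move both ways: P2ry14 and Pglyrp1 were called with WT FoxP3, Synj2, Fdx1 and Sgk1 with A384T, and AA467197 with neither (adjusted p = 0.053 and 0.214).

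Between R397W and WT FoxP3, 459 genes differed, whereas no gene differed between R397W and mock. That 2 arrays are too few to call changes as large as those of WT FoxP3 is argued against, since 2 WT arrays against the same 3 mock arrays called at least 402 genes; changes well below those of WT FoxP3 are not excluded, as 2.33% of simulated genes changed by 0.5 were recovered in R397W over mock. Little FoxP3 protein may also give such a profile. Cells without the vector would give one as well, but the sort for the vector's GFP selects against them. The Foxp3 probe set was at 0.037 in WT over mock and so did not report the transduced gene in cells sorted for this GFP. Little FoxP3 protein therefore cannot be told apart from a form of FoxP3 that is present and changes no gene at this precision. The R397W cells were sorted for GFP as the others were, but no protein was measured in the data used here.

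Of the 10092 probe sets with no gene or several genes listed, control probe sets left out, 100 differed between WT and mock (57 higher, 43 lower), 67 between A384T and mock and 0 between R397W and mock. The array's control probe set for the 3' end of the transferrin receptor, a receptor for iron uptake, was higher by 1.71 in WT over mock, with group means of 1.72 for WT, 0.80 for A384T and -0.05 for R397W. The control probe sets for other parts of the same transcript had smaller means, with 0.895 for WT and 0.63 for A384T at the 5' end and 0.632 for WT and 0.156 for A384T in the middle.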

How the results depend on the processing

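Settings chosen after the data were seen were a filter on the upper part of the genes by standard deviation, all probe sets, the arrays numbered 1 left out, robust or trend alone in eBayes, and slopes with the block. The filters on mean signal at the 30th and 50th percentiles, the highest-mean probe set and a repeated quantile normalization were not run, because the centred values hold no levels; signal over background is unknown for the same reason. No called result changed direction in any setting in which it was tested again. Of 232 called results of named genes, 75 were called in all settings in which they were tested again, and of 33 called lists, 3 were; neither was tested again with all probe sets or the 2-fold minimum. The estimated correlation ended 30 list calls, and leaving out the arrays numbered 1 ended 102 gene calls and 4 list calls. Trend alone ended 73 gene calls, trend with robust 66, only 2 groups in the fit 66, leaving out 1 array 22 to 62, the mean of probe sets 22, the filter on standard deviation 10, array weights 2, and robust alone, centring of arrays and the block 0. With the array number as a replicate block, counts in WT over mock, A384T over mock, A384T over WT, R397W over WT and R397W over A384T were 1849, 1839, 159, 1460 and 1460, and apart from the values given beside results above the block ended no call. Trend with robust gave 333, 245, 224 and 184 (A384T over WT within 1.5 times), and the counts with trend alone stayed within 1.5 times. With only 2 groups in the fit the counts were 343 (A384T over mock), 12 (A384T over WT), 203 and 113 (R397W over WT and over A384T), with fewer arrays to estimate the spread. A 2-fold minimum left 391 (WT over mock) and 342 (A384T over mock). Without the arrays numbered 1 the counts, in the order of the block, were 393, 259, 3, 168 and 102. Leaving out 1 array at a time gave 402 to 676 in WT over mock, 345 to 535 in A384T over mock, 0 to 0 in R397W over mock, 5 to 26 in A384T over WT, 168 to 478 in R397W over WT and 126 to 411 in R397W over A384T. In the same way the slope with the block ranged from 0.848 to 0.961 for A384T and from -0.108 to 0.0289 for R397W. The slope without the block, which was biased on simulated data, ranged from 0.908 to 1.13 and from -0.254 to 0.0299. At the genes called in WT over mock, with no noise removed, the A384T slope was 0.853. Those genes were picked on the same WT arrays, which favours a lower slope. Apart from fewer arrays or groups, and fewer genes with the 2-fold minimum, the cause was not tested.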

Other observations

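The tests of the arrays numbered 1, and the genes named in the next paragraph, were chosen only after the values were seen, whereas the regrouping of the arrays was fixed before.

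The list of chemokine receptors and homing genes was not called as a set between A384T and WT FoxP3 (adjusted p = 0.257, and 0.151 with the array number as a block). Of its 26 genes, 0 were called without the block (4 higher and 1 lower adjusted over the list alone), and 3 were higher and 2 lower with it. Among receptors and T cell genes called only with the block, Itga4, an integrin chain (1.83 ± 0.49, adjusted p = 0.443, blocked 0.000278), and the chemokine receptors Cxcr3 (1.32 ± 0.37, 0.526, blocked 0.00297) and Cxcr6 (1.36 ± 0.27, 0.156, blocked 0.0412) were higher with A384T. Ccr4, a chemokine receptor, was lower (-0.59 ± 0.23, adjusted p = 1.00, blocked 0.0314), as was Itgae (-1.10, blocked 0.0127). The phosphodiesterase gene Pde3b was at 1.07 ± 0.18 (adjusted p = 0.063, blocked 0.00439), Irf8 at 0.98 ± 0.34 (0.891, blocked 0.0288) and the IL-18 receptor chain Il18rap at 0.94 ± 0.23 (0.358, blocked 0.04). That higher genes prevail here comes from the choice of genes, as 75 genes were higher and 84 lower with the block.

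The arrays numbered 1 stood apart in all groups. Set against the other arrays with the groups as a block, 3606 genes differed, 1821 higher and 1785 lower, and 23 of 31 cell cycle genes were higher, among them Ccnb2 (1.80), Ccna2 (1.77) and Mki67 (1.27). Of 17 glycolysis genes 12 were lower, among them the glucose transporter Slc2a3 (-2.13), Pfkp (-1.75) and Tpi1 (-1.59). The set tests gave an adjusted p = 3.92e-10 for cell cycle (adjusted p = 0.529 with an estimated correlation) and 2.33e-09 for glycolysis (adjusted p = 0.293 with an estimated correlation).

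A more proliferative state of the cells of the arrays numbered 1 stays open: the cell cycle median was higher there in all 4 groups, by at least 0.164, but this restates the observation and tests nothing. A difference in labelling or hybridization may contribute, as the median of 18 hybridization controls was higher on the arrays numbered 1 in all 4 groups. The differences were 0.084 for mock, 0.00868 for WT, 0.26 for A384T and 0.162 for R397W. In 3 groups they were above the gap between the other arrays. R397W, with 2 arrays, has no such gap and counts among the 3 by construction. RNA degradation stays open, since the 5' minus 3' control value was lower on the array numbered 1 in 4 of 4 groups for actin and in 1 of 4 groups for Gapdh and for pyruvate carboxylase. No design group separates these explanations, and no biological one could be tested on its own.

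Regrouping the arrays bears on the counts of calls. Of the 10 splits of 6 arrays, the real split called 659 genes in WT over mock and 577 in A384T over mock, and the highest other called 0, so that 1 split reached each count; 10 splits are too few for a share under 0.05. For lists, the real split called 9 in WT over mock (highest other 9, reached by 2 splits with the real 1), 5 in A384T over mock (highest other 7, reached by 4) and 7 in A384T over WT (highest other 6, reached by 1), again with too few splits. Among the 4 splits that part all same-numbered pairs, the highest other called 5, 4 and 3 lists. The other splits that call as many lists as the real one leave pairs together, but so do most of the other splits. This therefore does not show that the array numbers are the cause. The list calls at the preset correlation are to be read with those at an estimated one.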
